A study of Arabidopsis thaliana with 4 samples.

How the data were processed

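Expression was measured on 4 Agilent 2-colour arrays of Arabidopsis thaliana seedlings. Per the labels, each array held wild-type Col RNA in the Cy3 channel and RNA of seedlings with the genotype vim1,2,3 in the Cy5 channel. The vim1,2,3 seedlings are, per the series title, a triple mutant of VIM1, VIM2 and VIM3. The labels describe total RNA extracted with a column kit, then linearly amplified and dye-labelled. The orientation of the dyes was the same on the 4 arrays, so a ratio of Cy5 over Cy3 is a ratio of RNA labelled vim1,2,3 over Col. The 4 arrays shared a slide and the scanner settings, so no technical batch could be tested. The series describes the 4 arrays as independent biological samples.

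The scanner images had been quantified with Agilent Feature Extraction 10.7.3.1, per the file headers. Spot brightness is a linear intensity per the file headers, deposited as the median over the pixels of each spot and of the area around it. The deposited processed intensity of each channel had been background-subtracted with spatial detrending and dye-normalized with a linear and a lowess step, per the file headers. The scanner's own log ratio is the log10 of processed red over processed green, per the file headers. The deposited series matrix holds a log2 ratio per probe and array. Set against the scanner's log ratio of the same array, its values had the same direction and scale, with correlations across probes of 0.998 to 0.999. Its medians were -0.09, 0.01, -0.04 and -0.03 on arrays 1 to 4, and its normalization and centring are not given in the sources used here. Many of its values are blank, and 99.6% to 99.9% of those given per array belong to probes well above background in both channels. Over 36062 probes the median absolute difference from the scanner's log ratio was 0.00999, and 7 probes differed by more than 1 on an array. Those 7 probes, the VIM3 and VIM5 probes among them, were not used in the alternative that starts from the series matrix.

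The values were recomputed from the median intensities. The planned design named mean signals, and the files gave medians, which were used in their place. Background was corrected with normexp and an offset of 50, fitted on all spots. Each array was then normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3, with the package data.table (version 1.17.8) for reading. Control spots (1417 of 45220 per array) and spots marked as outliers by the scanner software were left out afterwards. The spots of a probe were averaged, which concerned 50 probes with 5 spots each. No values were scaled between arrays.

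Probes were named through the accession in the scanner files, without versions, against the RefSeq gene table of assembly TAIR10.1. Of 43603 probes, 34185 matched a current locus, for 25347 loci, and 9418 did not match. The array's header names an older genome build, so the table was used for names and gene order only and no coordinates are given. A probe was tested where it was well above background in at least 1 channel on at least 3 of the 4 arrays. A gene was represented by the brightest of its tested probes over both channels, which left 20464 genes. Of 280 called genes with another tested probe, 1 had a probe of the opposite sign at 2-fold or more. Saturated spots were kept, and the chosen probe of 31 genes was saturated in both channels on all arrays.

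The test was limma's lmFit with an intercept on the 4 log2 ratios, followed by eBayes, with Benjamini-Hochberg adjustment over all genes tested. A gene was called higher or lower at an adjusted p under 0.05 and a change of at least 2-fold. The ratio pairs the RNAs hybridised on the same array, so the array acts as the replicate block. Where a channel was not well above background, or saturated, on all 4 arrays, the change is a bound. It compares the bright RNA's mean with a mean over arrays of the higher of the dim probe's signal and the lowest signal well above background, after loess and Aquantile. Such a bound stays open to dye bias and makes no allowance for the spread over arrays. For VIM5 and the dimmer ROS1 probe it equals the measured ratio.

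A set of 18 gene lists with 247 genes was fixed before the data were examined, as were the rule for named genes, the tests and most alternatives. The rule named the VIM family, the 12 largest rises and 8 largest falls among called genes of the same sign on 4 arrays, and up to 4 called members of each list with the smallest adjusted p. Where no member was called, the 2 with the smallest p were named as not called. Lists were tested with camera at a preset correlation of 0.01 and adjusted over 17 lists. Camera with an estimated correlation and fry were run beside it. The list of ONSEN and EVADE retrotransposon copies had no member matched to a probe, and a test of transposable element genes was not run for the same reason, so both are not analysed here. A planned test by distance from the centromeres was not run without coordinates of the array's build. Gene order, chosen after the data were seen, took its place: each chromosome's centre was the window of 401 annotated genes richest in pseudogenes, and genes within 800 annotated genes on either side were compared with the rest by a two-sided Fisher's exact test.

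Alternatives covered the background correction, the scanner's processed signals, the series matrix, median centring, scaling between arrays, filters on dim probes, the choice of probe, the thresholds, the variance model, array weights, unpaired channels and leaving out each array. The procedure was tested on simulated data for this comparison with 20464 genes and 4 arrays. It called 62% of genes changed by 1.5 on the log2 scale, 70% of those changed by 2, 94% of those changed by 3 and 100% of those changed by 4, with 3 false calls. The simulated noise was independent between genes and arrays, without dye effects or differences between arrays. The false calls therefore do not carry over to the real arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.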

Results

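Transcripts of wild-type Col seedlings and of seedlings labelled vim1,2,3 were compared on 4 arrays, with both RNAs of a replicate on the same array. Seedlings were 14 days old, grown with 16 h of light and 8 h of dark, and harvested 6 h after the lights came on. The median spot signal was 637 to 1270.5 for Col and 949 to 1718 for the RNA labelled vim1,2,3. Between 75.8% and 85.2% of spots were well above background in Col, and between 68.6% and 81.5% in the RNA labelled vim1,2,3. The number of arrays limits the precision, and the p-values measure the spread of these 4 biological samples. Without a dye swap, a dye effect on a probe cannot cancel. Each value is a log2 ratio of RNA labelled vim1,2,3 over Col, as a mean ± SD over arrays.

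The genes that the genotype names were examined before all others. VIM1, VIM2 and VIM3 encode RING-finger proteins that bind methylated DNA and are needed to maintain CG methylation. VIM1 (AT1G57820) was 3.37-fold lower in the RNA labelled vim1,2,3 (-1.76 ± 0.77, SD, n = 4, adjusted p = 0.025). It was below 0 on 4 of 4 arrays, at -2.22, -2.46, -1.61 and -0.74, and another VIM1 probe averaged -2.19. VIM2 (AT1G66050) was at -1.41 and -1.31 on arrays 1 and 2 and at 1.82 and 1.11 on arrays 3 and 4 (0.05 ± 1.66, adjusted p = 0.959). VIM3 (AT5G39550) was at -1.06 and -1.29 on arrays 1 and 2 and at 1.62 and 0.25 on arrays 3 and 4 (-0.12 ± 1.34, adjusted p = 0.881). VIM4 (AT1G66040) had values of -0.96, -1.63, 2.22 and 0.61 (0.06 ± 1.72, adjusted p = 0.954), and another VIM4 probe had 0.14, -1.10, 2.36 and 1.09. The mean of VIM2 turned to -0.14 and that of VIM4 to -0.11 with the scanner's processed signals. VIM5 (AT1G57800) was at least 3.56-fold lower (adjusted p = 0.00311), with the RNA labelled vim1,2,3 not well above background on all 4 arrays. VIM6 (AT4G08590) was not called (0.40 ± 0.70, adjusted p = 0.357). Of the 6 measured family members, 0 rose, 2 fell and 4 were not called, and 2 fell when adjusted over the list alone. The list did not stand apart from other genes (camera, adjusted p = 0.447).

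VIM2 and VIM3 went against the genotype label on arrays 3 and 4, so the samples are described here as RNA labelled vim1,2,3. Where the probes of VIM1, VIM2 and VIM3 lie relative to the mutations is not given in the sources used here, and a probe outside a disrupted part would check nothing. The VIM1 call was lost without array 1 (adjusted p = 0.0762) and without array 3 (adjusted p = 0.127). In the series matrix, the values of the VIM3 and VIM5 probes differed from those of the scanner files and were not used, and those of the VIM2 probe were blank.

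**Figure D1:**
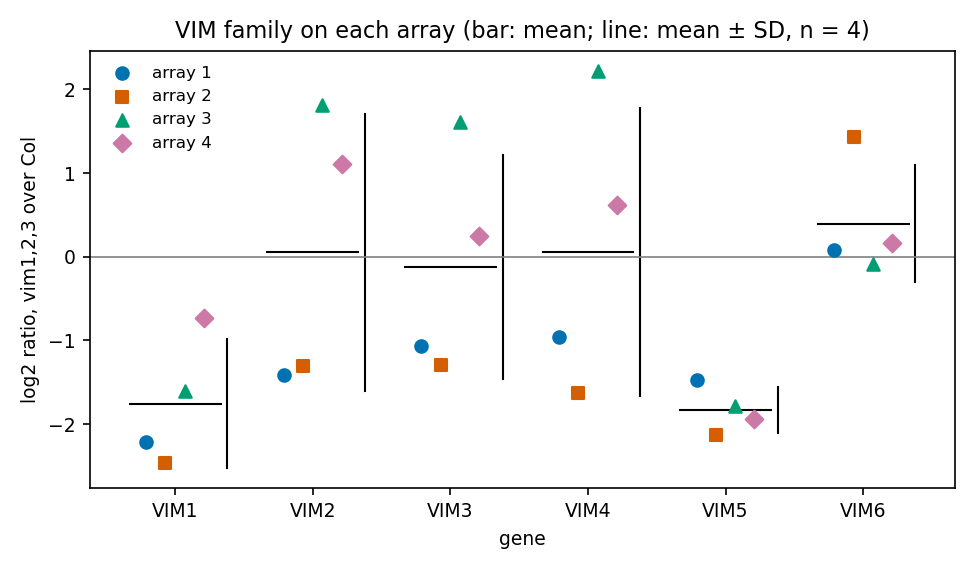
Log2 ratio of RNA labelled vim1,2,3 over Col (y axis) of the 6 VIM genes (x axis) on each of the 4 arrays, with the mean as a bar and the mean ± SD as a line. VIM1 and VIM5 lie below 0 on 4 of 4 arrays, while VIM2, VIM3 and VIM4 lie below 0 on arrays 1 and 2 and above 0 on arrays 3 and 4.

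The comparison of the genotypes asks which transcripts depend on the VIM proteins. The largest rise was that of AT4G08593, at least 41.1-fold (5.36 ± 0.20, SD, n = 4, adjusted p = 4.12e-05), with its signal in the RNA labelled vim1,2,3 saturated on all 4 arrays. AT1G59930 and AT1G59920 rose 35.7-fold and 34.6-fold, at 5.16 ± 0.08 and 5.11 ± 0.16, each with an adjusted p of 4.12e-05. AT4G29200 rose 35.4-fold (5.14 ± 0.09), AT2G05915 34.4-fold (5.10 ± 0.16) and AT3G54730 32.8-fold (5.03 ± 0.13). AT5G29050, AT3G43572, AT4G08691, AT1G18130, MRD1 (AT1G53480) and AT3G43833 rose by log2 ratios of 4.79 to 5.06, with adjusted p of 4.12e-05 to 0.000156. AT1G59930 and AT3G43833 were saturated in the RNA labelled vim1,2,3 on 1 of 4 arrays, which caps the ratio of that array. These 12 genes were above 0 on 4 of 4 arrays by the rule that chose them. They kept their call without each array in turn.

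ROS1 (AT2G36490), a DNA glycosylase that removes methylated cytosine, fell 11.1-fold (-3.47 ± 0.22, SD, n = 4, adjusted p = 0.000119) and had the largest fall among the genes called. Its signal in the RNA labelled vim1,2,3 was well above background on 2 of 4 arrays. Another ROS1 probe, with that RNA not well above background on any array, was at least 5.73-fold lower. AT2G13550 fell 8.65-fold (-3.11 ± 0.17, adjusted p = 0.000157). VSP2 (AT5G24770) and VSP1 (AT5G24780), vegetative storage proteins induced by jasmonate, fell 6.87-fold and 6.51-fold (-2.78 ± 1.00 and -2.70 ± 0.95, adjusted p = 0.0143 and 0.0136). AT3G46490, MUB5 (AT1G77870), a membrane-anchored ubiquitin-fold protein, and AT3G09160 fell at -2.64, -2.58 and -2.50. AT1G26790 fell at -2.40 ± 1.05 (adjusted p = 0.0228). Without array 4, the calls of VSP2 (adjusted p = 0.0793), VSP1 (0.0767) and AT1G26790 (0.0852) were lost, and that of AT1G26790 was also lost without array 3 (0.123).

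In all, 664 of 20464 genes rose and 437 fell, with a median log2 ratio of 1.53 among those that rose and -1.23 among those that fell. A change of at least 4-fold was found for 212 genes that rose and 20 that fell, and 41 genes rose at least 16-fold. Of the genes that rose, 651 were above 0 on 4 of 4 arrays, and of those that fell, 436 were below 0 on 4 of 4 arrays. Col was not well above background on any array for 20 of the genes that rose, and the RNA labelled vim1,2,3 was not for 8 of those that fell. Rises were 60.3% of the calls, but 42.2% with the scanner's processed signals, 46.8% with the series matrix and 42.2% with median centring, where the median of all genes moved from -0.05 to -0.14, -0.11 and -0.16. Without array 1, 3 or 4 the counts were 341, 182 and 197 genes higher and 223, 33 and 58 lower. Without array 2 they were larger, at 988 higher and 595 lower. Of the genes called higher without array 2, 80.4% were above 0 on it, against 98.8%, 100% and 99.5% for arrays 1, 3 and 4. These shares come from unlike sets of genes. The 988 genes had a median of 0.67 on array 2. The shorter sets for arrays 1, 3 and 4 had medians of 2.16, 3.20 and 3.02 on the array left out. The shares therefore do not compare the arrays on the same genes. In each fit that left out an array, 162 and 20 of the genes were called, the 41 genes of 16-fold and more among them.

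**Figure D2:**
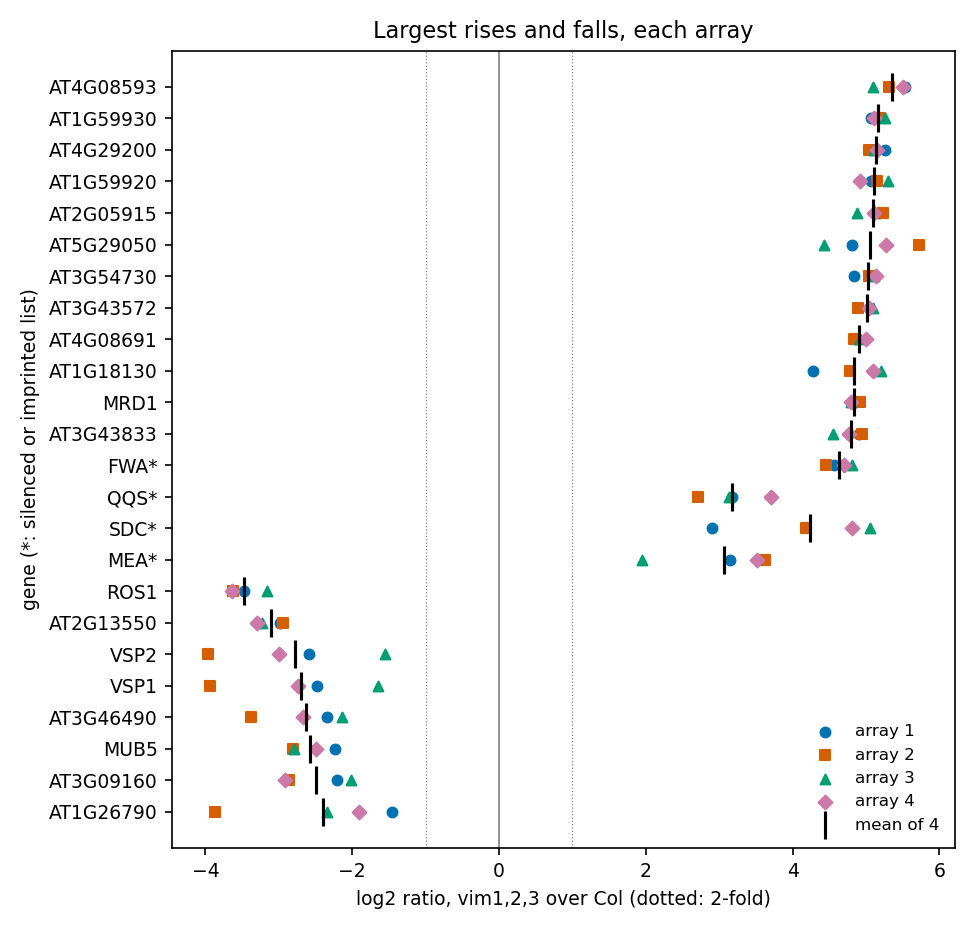
Log2 ratio of RNA labelled vim1,2,3 over Col (x axis) on each of the 4 arrays for the 12 largest rises, 4 genes of the silenced or imprinted list and the 8 largest falls (y axis), with the mean of 4 arrays as a vertical bar and 2-fold changes dotted. FWA lies between 4.46 and 4.82 and ROS1 between -3.64 and -3.16.

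Of 13 genes known to be silenced by DNA methylation or imprinted, 7 were measured and 5 of these rose. FWA (AT4G25530), a homeodomain gene kept silent in wild-type seedlings by methylated promoter repeats, rose 24.8-fold (4.63 ± 0.16, SD, n = 4, adjusted p = 4.91e-05). SDC (AT2G17690), an F-box gene under methylated tandem repeats, rose 18.9-fold (4.24 ± 0.96, adjusted p = 0.0024). QQS (AT3G30720), a regulator of starch content, rose 9.06-fold (3.18 ± 0.41, adjusted p = 0.000512). MEA (AT1G02580), an imprinted Polycomb gene, rose 8.34-fold (3.06 ± 0.77, adjusted p = 0.00458), with Col well above background on 2 of 4 arrays. The fifth was MPC at 2.06, and 0 fell, while HDG10 (0.87) and AGL87 (-0.79, below 0 on 4 of 4 arrays) were not called. The count was also 5 when adjusted over the list alone. The median of the 7 was 3.06 and the list rose against other genes (camera, adjusted p = 5.88e-05), but not past the threshold with an estimated correlation (adjusted p = 0.296). The test against no change, by fry, gave an adjusted p of 0.00106. A rise helps a silent gene to be measured, and the 6 members too dim to be tested lay between -0.09 and 0.33. Without the filter on dim probes the median of the 13 was 0.33 (camera, adjusted p = 0.000854).

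Of the DNA demethylation genes, ROS1 fell and 9 of 10 measured members were not called, with the same count adjusted over the list alone. The list's median was -0.35 (camera, adjusted p = 0.142), and fry gave an adjusted p of 0.00298. Of the DNA methylation and RNA-directed DNA methylation machinery, 0 of 27 measured members were called by limma, also when adjusted over the list alone. At an unadjusted p under 0.05, 1 was above 0 and 6 were below. NRPE1 (AT2G40030), the largest subunit of RNA polymerase V, was at -0.96 ± 0.25 (SD, n = 4, adjusted p = 0.0238), short of 2-fold, and IDN2 (AT3G48670), an RNA-binding protein of the same pathway, at -0.75 ± 0.37 (adjusted p = 0.05). NRPE1 passed 2-fold with the scanner's processed signals (-1.12), the series matrix (-1.12), median centring (-1.21), array weights (-1.01) and without array 2 (-1.07). The 3 probes of IBM1, a histone demethylase gene, differed, at 0.25, -2.19 and -1.47. The median of this list was -0.29 (camera, adjusted p = 0.142), and the camera test passed without array 2 (adjusted p = 0.0303) and with the mean of all probes of a gene (0.036). With an estimated correlation on the 4 arrays camera gave an adjusted p of 0.744.

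Genes of salicylic acid defence and immune receptors had a median of 1.41 and rose against other genes at the preset correlation (camera, adjusted p = 0.000103), but not past the threshold with an estimated correlation (adjusted p = 0.725). PR1 (AT2G14610), a secreted marker of salicylic acid responses, rose 7.97-fold (3.00 ± 0.98, SD, n = 4, adjusted p = 0.0105). PR2 (AT3G57260), a glucanase of the same response, rose 4.32-fold (2.11 ± 0.84, adjusted p = 0.0196). The transcription factor gene WRKY38 (AT5G22570) rose 3.68-fold (1.88 ± 0.86, adjusted p = 0.0263) and the receptor kinase gene FRK1 (AT2G19190) 2.63-fold (1.40 ± 0.58, adjusted p = 0.026). Of 16 measured members, 7 rose, 0 fell and 9 were not called, and 9 rose when adjusted over the list alone. The members below 0 were FMO1 (-0.52) and WRKY70 (-0.62, below 0 on 4 of 4 arrays, adjusted p = 0.0429). The WRKY70 probe was saturated in the RNA labelled vim1,2,3 on all 4 arrays and in Col on 3 of 4 arrays. Its ratio and p therefore do not measure a fall. The test of the list against no change, by fry, gave an adjusted p of 0.139. The list's median was 2.58 on array 1 against 0.44, 0.76 and 0.90 on the other arrays, and 1.02 without array 1. Without array 3 or array 4 the calls of PR1, PR2, FRK1 and WRKY38 were lost, with adjusted p of 0.0653 to 0.134, and without array 1 those of FRK1 (0.073) and WRKY38 (0.0762).

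Flavonoid and anthocyanin synthesis genes had a median of -1.22, or -0.67 without array 2, and fell against other genes at the preset correlation (camera, adjusted p = 0.000575), but not past the threshold with an estimated correlation (adjusted p = 0.725). F3H (AT3G51240), flavanone 3-hydroxylase, fell 3.82-fold (-1.93 ± 0.97, SD, n = 4, adjusted p = 0.0302), and DFR (AT5G42800), dihydroflavonol reductase, 3.58-fold (-1.84 ± 0.59, adjusted p = 0.0139). PAP1 (AT1G56650), a MYB activator of anthocyanin genes, fell 3.17-fold (-1.67 ± 0.91, adjusted p = 0.0358), and CHI (AT3G55120), chalcone isomerase, 2.47-fold (-1.30 ± 0.60, adjusted p = 0.0316). Of 10 measured members, 4 fell, 0 rose and 6 were not called, and 6 fell when adjusted over the list alone. The test of the list against no change, by fry, gave an adjusted p of 0.139. The median was -2.33 on array 2 against -0.37, -0.97 and -0.70 on arrays 1, 3 and 4. Without array 4 the 4 calls were lost (adjusted p of 0.0747 to 0.129), without array 3 those of F3H, CHI and PAP1 (0.137 to 0.155), without array 1 that of CHI (0.0807) and without array 2 that of PAP1 (0.0598).

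**Figure D3:**
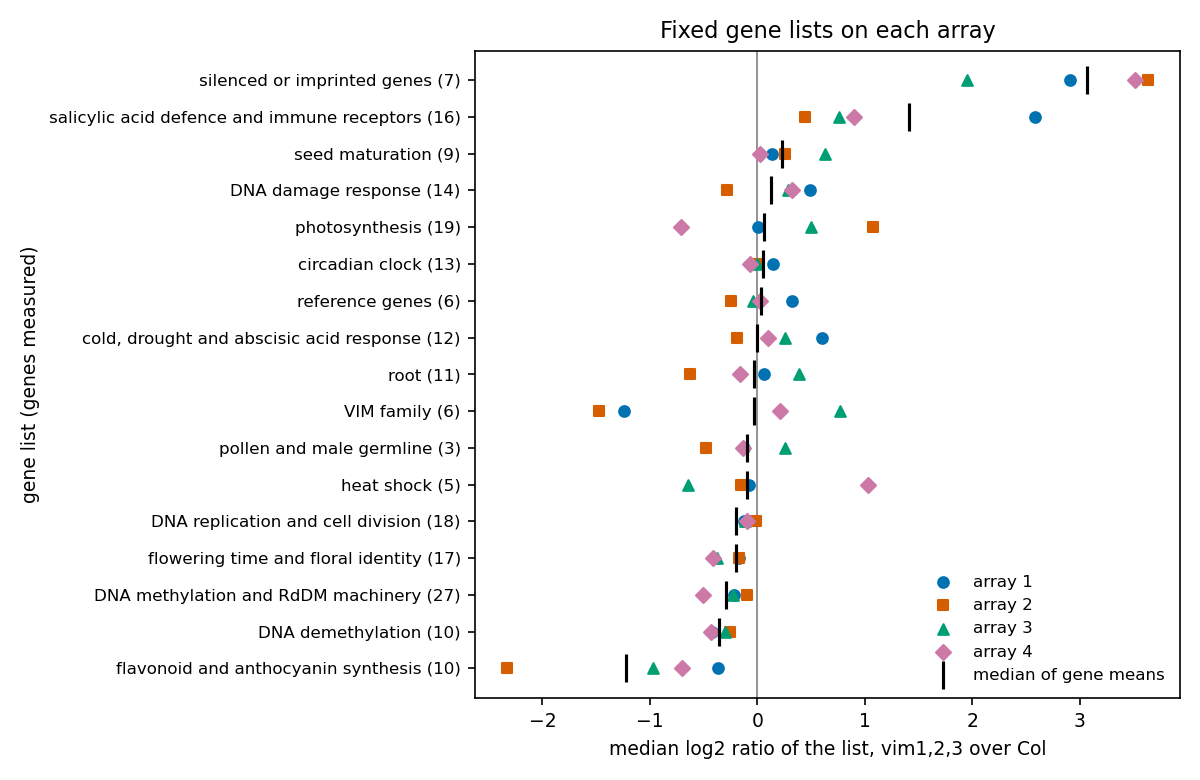
Median log2 ratio of RNA labelled vim1,2,3 over Col (x axis) of the 17 lists with measured genes (y axis, number measured in brackets) on each of the 4 arrays, with the median of the gene means as a vertical bar. The silenced or imprinted list lies between 1.95 and 3.63, the salicylic acid list between 0.44 and 2.58, and the flavonoid list between -2.33 and -0.37.

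Among flowering time and floral identity genes, AP1 (AT1G69120) and FUL (AT5G60910), MADS-box genes of floral meristems, fell at -1.56 ± 0.62 and -1.71 ± 0.78 (SD, n = 4, adjusted p = 0.0233 and 0.0269). The other 15 of 17 measured members were not called, FLC (-0.17) and FT (-0.17) among them, with the same counts adjusted over the list alone (median -0.20, camera, adjusted p = 0.281). FLC was dim, its RNA labelled vim1,2,3 being well above background on 2 of 4 arrays. Its other probes were at -1.43 and -0.72, below 0 on 4 of 4 arrays. For these probes that RNA was not well above background on any array. AP1 lost its call without array 1 (adjusted p = 0.0628) and array 3 (0.13), and FUL without array 3 (0.134) and array 4 (0.106). Of the circadian clock genes, ELF4 (AT2G40080), a part of the evening complex, rose 2.22-fold (1.15 ± 0.61, adjusted p = 0.0397), and 12 of 13 were not called, as when adjusted over the list alone. On array 2 the dawn genes CCA1 and LHY were at -2.16 and -2.72 and PRR7 at 2.18. The ELF4 call was lost without array 1 (adjusted p = 0.0753), array 3 (0.162) and array 4 (0.109). The clock list's median was 0.05, or -0.08 with the scanner's processed signals and the series matrix and -0.17 with median centring (camera, adjusted p = 0.838). Of the photosynthesis genes, 0 of 19 were called by limma, also when adjusted over the list alone, and at an unadjusted p under 0.05, 0 were above 0 and 5 below. These 5, LHCB5, RBCS1A, RCA, GAPA and GAPB, were saturated in the RNA labelled vim1,2,3 on all 4 arrays, which limits their ratios, and their other probes lay at 0.17 and 0.60 (LHCB5), -0.20 to 0.53 (RBCS1A), -0.13 to 0.29 (RCA), 0.13 to 0.18 (GAPA) and 0.33 and 0.39 (GAPB). GAPA (-0.66 ± 0.04) and RBCS1A (-0.64 ± 0.12), enzymes of carbon fixation, were not called, and no fold is given. GAPA was at 0.18 with probes not saturated in both channels and RBCS1A at 0.13 with the mean of all probes. The photosynthesis median was 0.06, while camera pointed down (adjusted p = 0.859), and the medians of arrays 1 to 4 were 0.01, 1.07, 0.50 and -0.71.

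Of the DNA damage response genes, SMR7 (AT3G27630), a cyclin-dependent kinase inhibitor, rose 2.60-fold (1.38 ± 0.61, SD, n = 4, adjusted p = 0.0279), and 13 of 14 were not called. Adjusted over the list alone, 2 rose (camera, adjusted p = 0.447). Of 18 DNA replication and cell division genes, 0 were called by limma, also when adjusted over the list alone. The probes of MCM2 disagreed. The one used was at -0.48, and another was at 1.60, 1.31, 1.01 and 0.73 on arrays 1 to 4. The cytokinesis syntaxin KN (0.54 ± 0.34) and the helicase subunit MCM4 (-0.44 ± 0.18) had the smallest p, and at an unadjusted p under 0.05, 2 were above 0 and 1 below (camera, adjusted p = 0.67). Of the cold, drought and abscisic acid genes, DREB1A (AT4G25480), a cold-response activator, rose 2.26-fold (1.18 ± 0.52, adjusted p = 0.031), COR15A (AT2G42540), a chloroplast protectant, fell 2.45-fold (-1.29 ± 0.65, adjusted p = 0.0341), and 10 of 12 were not called, as when adjusted over the list alone (camera, adjusted p = 0.67). Of the heat shock genes, the small chaperone gene HSP17.4 (AT3G46230) rose 2.51-fold (1.33 ± 0.40, adjusted p = 0.0175), with Col well above background on 2 of 4 arrays, and 4 of 5 were not called, as when adjusted over the list alone. The heat shock median was -0.10 while camera pointed up (adjusted p = 0.683). SMR7, DREB1A and COR15A lost their calls without array 3 (adjusted p of 0.131 to 0.143) and array 4 (0.069 to 0.109), SMR7 (0.0762) and DREB1A (0.0927) without array 1 and COR15A (0.0554) without array 2. HSP17.4 lost its call without array 1 (0.0591) and array 4 (0.0833).

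Lists for other organs served as a check on the makeup of the seedlings. Of 9 seed maturation genes, EM6 (AT2G40170), a late embryogenesis protein, rose 2.50-fold (1.32 ± 0.80, SD, n = 4, adjusted p = 0.0453), and 8 were not called, as when adjusted over the list alone (camera, adjusted p = 0.447). The EM6 call was lost without each array in turn (adjusted p of 0.0506 to 0.17). Of those not called, SESA3 (-0.69) was saturated in both channels and EM1 in the RNA labelled vim1,2,3 on all 4 arrays. Probes of these genes disagreed. Another SESA3 probe was also saturated in that RNA on all 4 arrays, but a further SESA3 probe was not well above background in Col on any array. The other EM1 probe was not well above background in either RNA. The other 6 seed members were too dim to be tested: SESA2 was at 0.06, 0.11, 3.57 and 0.95 and SESA5 at 0.01, -0.10, 3.05 and 1.83 on arrays 1 to 4, and SESA1, SESA4 and a CRU3 probe, with Col not well above background on any array, were also higher on arrays 3 and 4 than on arrays 1 and 2, while the CRA1 probes were not well above background in either RNA. This list therefore leaves the makeup of the seedlings on arrays 3 and 4 open. Of 3 pollen genes, 0 were called by limma, also when adjusted over the list alone. TIP5;1 was at -0.47 ± 0.21 (adjusted p = 0.0901) and HAP2 at -0.10 ± 0.30. At an unadjusted p under 0.05, 1 pollen gene was below 0 (camera, adjusted p = 0.67). TIP5;1 passed with the scanner's processed signals (-1.50, adjusted p = 0.0336), its signal in the RNA labelled vim1,2,3 being not well above background on all 4 arrays. Of 11 root genes, 0 were called, also when adjusted over the list alone. At an unadjusted p under 0.05, 1 root gene was above 0 and 2 below (camera, adjusted p = 0.802). PYK10, a root glucosidase, was at -1.06 ± 0.88 and the root hair gene COBL9 at 0.59 ± 0.40. The PYK10 probe was saturated in the RNA labelled vim1,2,3 on 2 of 4 arrays. PYK10 was at -2.21, -1.29, -0.39 and -0.37 on arrays 1 to 4. Its other probes, at -1.18 to -0.40, were also lower on arrays 1 and 2 than on arrays 3 and 4. Of 6 reference genes, 0 were called, also when adjusted over the list alone. UBC9 was at 0.92 ± 0.26 and EF1A at 0.84 ± 0.24, short of 2-fold (adjusted p = 0.0263 and 0.0302), and at an unadjusted p under 0.05, 2 reference genes were above 0 and 1 below. The latter, GAPC2 (-0.69), was saturated in both channels on all 4 arrays, and of its 5 probes never saturated in both channels, 4 lay between 0.26 and 0.52 and 1 at -0.21. UBC9 passed 2-fold without array 2 (1.04, adjusted p = 0.0245). The probe used for UBQ10 (0.34) was saturated in the RNA labelled vim1,2,3 on 3 of 4 arrays, and its 10 other probes lay between 0.70 and 1.06, above 0 on 4 of 4 arrays. The median of the reference genes was 0.03, or -0.05 with median centring, -0.02 with the scanner's processed signals, -0.09 without array 1 and 0.39 with the mean of all probes (camera, adjusted p = 0.783). It rests in part on the saturated probes of GAPC2 and UBQ10. With an estimated correlation, 0 of 17 lists passed camera, against 3 with the preset correlation, and 1 had an unadjusted p under 0.05.

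Genes near the pseudogene-rich centre of a chromosome rose more often than others. Within 800 annotated genes of a centre, 145 of 1986 tested genes rose (7.30%), against 519 of 18478 elsewhere (2.81%), an odds ratio of 2.73 (95% interval 2.24 to 3.30, two-sided Fisher's exact test, p = 2.87e-21). Among the 116 genes within 200 annotated genes of a centre, 22 rose (19.0%). Genes that fell had an odds ratio of 1.41 (95% interval 1.04 to 1.87, two-sided Fisher's exact test, p = 0.0218), with an exact p of 0.0525 within 400 genes and 0.205 within 1200. Without array 1, 2, 3 or 4 the odds ratio for genes that rose was 4.19, 2.20, 6.13 and 5.28. Fisher's test treats genes as independent, but genes called higher had neighbours called higher more often than in shuffles of the calls. Its intervals are therefore likely too narrow and its p-values too small, and they do not measure the spread over arrays.

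**Figure D4:**
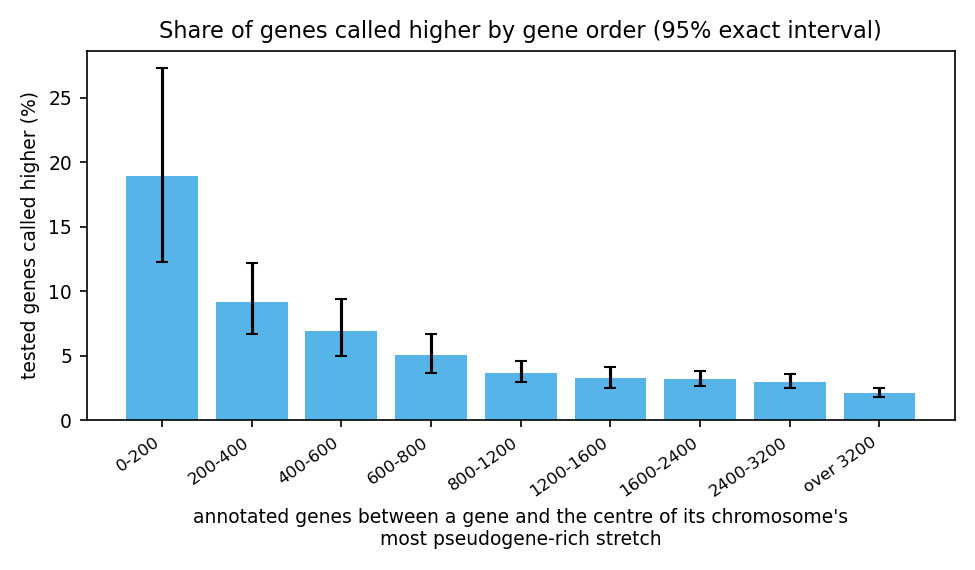
Share of tested genes that rose (y axis, percent, with 95% exact intervals) by the number of annotated genes to the centre of the chromosome's most pseudogene-rich stretch (x axis). The share is 19.0% within 200 genes and 2.09% beyond 3200 genes.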

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

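The tests of exchanged RNAs, interchanged probe names, shared VIM2 and VIM4 signal, genes with dim Col without background correction and probes without a current locus were chosen after the values were seen, and the other tests before.

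VIM6 on array 2 stood apart at 1.44, with the other arrays between -0.09 and 0.16. PAP1 on array 1 stood apart at -0.31, with the other arrays between -2.29 and -2.01. These were 2 of 79 genes and lists examined for a lone array, where chance gives about 3.95. Among probes that matched no current locus, 526 of 6235 tested were higher (8.44%), against 3.48% of probes with a locus (odds ratio 2.55, two-sided Fisher's exact test over probes, p = 6.83e-57). Probes that share a transcript are not independent, so the p-value of this test is likely too small. Among probes known by their probe ID alone, 153 of 980 were higher (15.6%).

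The rises and falls lacked a dye swap, so dye bias was weighed. Another tested probe of the same gene was above 0 for 91.9% of genes called higher (125 of 136), against 55.7% among genes not called. It was below 0 for 97.9% of genes called lower (141 of 144), against 44.3%. That argues against a bias of single probes as the source of the direction of these genes, as far as the probes of a gene differ in sequence. Probe sequences were not available, so overlap between the probes of a gene was not checked. They are 136 of the 664 genes called higher and 144 of the 437 called lower, and the rest could not be checked. The other probe reached 2-fold for 84 of the 136 and for 66 of the 144. Without background correction 100% of the 544 genes called higher and well above background in both channels on all arrays stayed above 2-fold, but the correction hardly acts on these and the test decides nothing. Of the 119 genes called higher with Col not well above background on at least 1 array, 118 (99.2%) were still called without the correction. Their median log2 ratio moved up by 0.056. However, the correction adds an offset of 50, against a median Col background of 39 to 43 over the arrays. Leaving the correction out could therefore hardly lower these ratios. The test does not decide whether the correction is the source of these rises. A bias of a whole transcript in both its probes stays open, and the 4 arrays have 8 orientations, too few for a share under 0.05: the real orientation called 1101 genes and the highest other 0 (1 orientation reached the real count), and for lists 3 and 4 (6 orientations did).

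VIM2, VIM3 and the brightest VIM4 probe were above 0 on arrays 3 and 4 and below 0 on arrays 1 and 2, while the other VIM4 probe was at 0.14 on array 1. Arrays 3 and 4 also had more spots well above background, at 85.2% and 84.3% in Col against 75.8% and 77.8% on arrays 1 and 2, and at 81.1% and 81.5% against 69.6% and 68.6% in the RNA labelled vim1,2,3. An exchange of the RNAs on array 3 alone or array 4 alone is argued against. At least 99.49% of genes called higher without that array were above 0 on it. The genes for array 3 were called with array 4 and the reverse, so this test does not cover an exchange on both. Ratios across genes correlated at 0.37 to 0.61 between arrays 1 or 2 and arrays 3 or 4. An exchange on both would turn true changes against each other there, but not a dye effect shared by the arrays. Interchanged probe names of VIM2, VIM3 and VIM5 in the scanner files do not account for both VIM2 and VIM3, since 2 of the 3 probes were above 0 on arrays 3 and 4, but stay open for 1 of them. Signal shared between the VIM2 and VIM4 probes stays open: VIM3, on another chromosome, spanned 2.90 between arrays, but its order over the arrays was not that of VIM2. Transcripts from the disrupted genes that differ between the plants used, and seedlings of another genotype on arrays 3 and 4 with the same raised genes, stay open and were not tested, as does a difference in labelling or hybridisation between these pairs of arrays.

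Array 2 had CCA1 at -2.16, LHY at -2.72, PRR7 at 2.18 and LHCB3 at 2.16. Dawn-phased and later-phased genes outside the clock list differed by 1.70 on array 2 (4 later-phased minus 8 dawn-phased genes), against 0.55, -0.19 and 0.97 on arrays 1, 3 and 4, although dawn-phased RVE7 (2.20) and later-phased BOA (-0.35) went the other way. A different time of harvest of the RNAs on array 2 is therefore a candidate explanation, and a clock altered in those plants stays open. The photosynthesis median on array 2 lay at percentile 100 of 10000 random lists matched on intensity, which argues against intensity-dependent normalization as the source on array 2. Array 2 was not alone: the photosynthesis median of array 3 lay at percentile 100 too, and that of array 4 at percentile 0. The median of array 4 (-0.71) was the value of an LHCB5 probe saturated in the RNA labelled vim1,2,3 on all 4 arrays and in Col on 3. That median is therefore limited by saturation. The other LHCB5 probes were at -1.04 and -1.52 on array 4.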

How the results depend on the processing

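The choice of unsaturated probes, the gene-order windows and the count of probes without a locus were chosen after the data were seen, and the other alternatives before. Over these alternatives, 1019 values of named genes and 298 of gene lists kept their direction and side of the threshold, 94 and 5 fell below it, 12 and 3 passed it, and 17 and 15 changed direction. The odds ratio by gene order stayed above 1 in each alternative, from 1.99 with adjusted p alone to 6.83 with treat, and was 4.04 within 400 genes and 2.07 within 1200. Genes lower numbered 813 with the scanner's processed signals and 876 with median centring, where the median of all genes lay lower at -0.14 and -0.16. By construction, looser or stricter thresholds moved the counts of genes higher and lower: adjusted p alone gave 1183 and 1211, treat against a log2 ratio of 1 gave 139 and 8, and 3-fold gave 313 and 79. Without the pairing of RNAs on an array (no replicate block, 4 against 4 channels), 396 genes were higher and 153 lower, with 394 and 153 of them called in the paired fit, and 3 lists passed, as in the paired fit. Leaving out an array gave 182 to 988 genes higher and 33 to 595 lower, and the cause was not tested. With an estimated correlation camera called 0 lists, against 3 with the preset correlation and 2 by fry. Scaling average intensities between arrays (Aquantile) leaves ratios as they are and moved nothing.

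Changes of direction concerned values that were not called, and the cause was not tested. VIM2 was at -0.14 with processed signals, -0.042 with median centring, -0.052 with scaling between arrays and -0.54 to 0.54 without an array. VIM3 was at 0.18 with array weights and -0.70 to 0.27 without an array. VIM4 was at -0.11 with processed signals, -0.11 with the series matrix, -0.19 with median centring, -0.026 with scaling and -0.66 to 0.63 without an array. GAPA was at 0.18 with probes not saturated in both channels, RBCS1A at 0.13 with the mean of all probes, and HAP2 at -0.22 to 0.030 without an array. The direction by camera turned for photosynthesis, with medians of 0.048 (processed signals), 0.064 (series matrix), 0.10 (median centring), 0.13 (scaling), 0.22 (mean of all probes), 0.18 (unsaturated probes) and -0.24 to 0.51 without an array. It turned for pollen with median centring (-0.050), for heat shock with the series matrix (-0.16) and with both channels well above background (-0.10), and without an array for root (-0.30 to 0.011), cold (-0.061 to 0.23) and heat shock genes (-0.30 to 0.14). The tests of transposable element genes and of distances of 2, 3 and 5 Mb from centromeres were not run. Pollen genes gave no list value with the series matrix. Dim signals limit VIM5, ROS1, FUL, FLC, PI, MEA, HDG10, IGMT3, EXPA22, FMO1, HSP17.4, TIP5;1 and HAP2, each well above background in the dimmer RNA on at most 2 arrays.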

Other observations

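The genes and runs named here, and the comparison of the series matrix with the scanner files, were chosen after their values were seen, while the test of neighbouring genes was chosen before.

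EXO70A2 (AT5G52340), a subunit of the exocyst, rose at 4.73 ± 0.32 (SD, n = 4, adjusted p = 6.2e-05), and HEI10 (AT1G53490), a RING-finger protein of meiotic crossovers, at 4.55 ± 0.24 (adjusted p = 6.11e-05). EXPA22 (AT5G39270), an expansin, rose at least 15.03-fold, with Col not well above background on any array, and UGT76C1 (AT5G05870), a cytokinin glucosyltransferase, at 3.94 ± 0.48. These 4 genes kept their call without each array in turn. Among falls outside the lists, PI (AT5G20240), a MADS-box gene of petals and stamens, was at -2.20 ± 0.69 (adjusted p = 0.0111), CER4 (AT4G33790), a reductase of wax synthesis, at -2.28 ± 0.75 (adjusted p = 0.0128) and JMT (AT1G19640), which methylates jasmonic acid, at -1.83 ± 0.87 (adjusted p = 0.0277). The calls of PI and JMT were lost without array 3 (adjusted p = 0.0803 and 0.137), and those of CER4 and JMT without array 4 (0.0643 and 0.1).

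Runs of at least 3 consecutive tested genes called higher numbered 8, the longest with 4 genes. Among others, they held the methyltransferase genes IGMT1 (2.04), IGMT2 (1.61), IGMT3 (1.34) and IGMT4 (1.70). They also held the wall-associated kinase genes WAK1 (1.58), WAK2 (1.36) and WAK3 (2.04). AT3G43572 (5.02), AT3G43574 (4.30) and AT3G43580 (3.09) formed a run whose calls held without each array in turn, and AT4G10910 (3.38), KELP (2.54) and AT4G10925 (1.25) another, of which AT4G10925 lost its call without array 1, 3 or 4 (adjusted p of 0.0641 to 0.0988). In the runs of IGMT and WAK genes, 6 of the 7 calls were lost without array 3 (adjusted p of 0.0605 to 0.145), the exception being WAK2 (0.049), which lost its call without array 4 (0.0647). Calls were also lost without array 4 for IGMT2, IGMT3, WAK1 and WAK3 (0.0822 to 0.14) and without array 1 for IGMT3, WAK1 and WAK3 (0.0605 to 0.0878).

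Of the genes called higher, 19.0% (126 genes) had a tested neighbour that was called higher too. In 10000 shuffles of the calls the mean was 6.35% and the highest 12.5%, and in shuffles that kept the share near chromosome centres the highest was 13.3%. These values are consistent with clusters of neighbouring genes raised together, as a hypothesis. Probes of tandem copies that share signal, such as those of IGMT1 to IGMT4, could add to the share and were not tested. Shuffles of the calls do not keep neighbouring members of a gene family together. Several runs were of this kind, such as the IGMT and WAK genes and CYP71B23, CYP71B3 and CYP71B24, and the share was not computed without them.

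The series matrix and the scanner files differed for the VIM probes. Its values for the VIM5 probe, -1.42, -1.52, 1.64 and 0.11 on arrays 1 to 4, lay within 0.0159 of the scanner's log2 ratios of the VIM3 probe on each array, and the next closest probe differed by 0.353. Its values for the VIM3 probe, -1.86, -1.99 and -1.22 on arrays 1, 3 and 4 and blank on array 2, lay within 0.00859 in size of the scanner's ratios of the VIM2 probe (-1.85, 1.99 and 1.23), but with the opposite sign on arrays 3 and 4. Its values for the VIM2 probe were blank on the 4 arrays, as they would be for the VIM5 probe, whose signal in the RNA labelled vim1,2,3 was not well above background on any array. VIM1, VIM4 and VIM6 differed little, VIM1 being at -2.97, -3.17, -1.85 and -1.01 in the series matrix and at -2.96, -3.17, -1.85 and -1.02 in the scanner files. Of 36062 probes compared, 2 differed by more than 1 on at least 2 arrays, those of VIM3 and VIM5, and the cause was not tested.

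AT5G34830 was at 0.10 and 0.38 on arrays 1 and 2 and at 5.14 and 4.94 on arrays 3 and 4, the pairs of arrays that VIM2 and VIM3 set apart, and was not called (2.64 ± 2.78, SD, n = 4, adjusted p = 0.118).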
